A study of Arabidopsis thaliana with 12 samples.

How the data were processed

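The series holds 12 one-colour Affymetrix arrays, with total RNA as the starting material and biotin as the label. The RNA came from seeds of Arabidopsis thaliana, in the Ler background and from 1 stock. Per the labels, seeds were treated with water or with 5 µM gibberellin for 3, 6 or 9 h. The form of gibberellin and the genotype of the stock beyond its background are not given in the sources used here. Each group has 2 arrays, lettered A and B. The deposited values are intensity values on a linear scale, MAS5 signals per the submitters' processing notes. The MAS5 version is not given in the sources used here. All 12 deposited columns hold 22810 probe sets with no missing value. The 2%-trimmed mean signal of every array is 100 (the largest differs from the smallest by a factor of 1.00002), so the arrays had been scaled to a common mean before deposition. They were therefore taken to log2 as deposited, with no further normalization and no offset. Such scaling removes any change in the total amount of RNA per seed, and values near the floor spread widely on the log2 scale.

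After 64 hybridisation and other control probe sets were left out, a probe set was kept when at least 2 of the 12 arrays lay above the 40th percentile of all log2 signals, a signal of 16; 15766 of 22746 (69.3%) were kept. Probe sets were named from the platform annotation supplied with the reference: 13513 name exactly 1 gene, 503 name several and 8730 are unnamed here. Of the 13513, 13436 matched the RefSeq table of the assembly TAIR10.1 and 77 did not; no coordinates were used. No gene was named from a probe set that names several.

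The groups were compared with limma 3.58.1 in R 4.3.3: a linear model with 6 group means was fitted to all 12 arrays, which leaves 6 residual degrees of freedom. The variances were moderated with an intensity trend (prior degrees of freedom 5.53). Contrasts were gibberellin against water at each time, their average, the difference between the effects at 9 h and 3 h, water at 6 h and at 9 h against 3 h, and gibberellin at 9 h against 3 h. All tests are two-sided. The p-values were adjusted by the Benjamini-Hochberg method over the 15766 probe sets of a comparison, and an adjusted p under 0.05 counts as past the test. Changes are given as log2 differences ± SE from this model, and signals as means ± SD of 2 arrays. The 8 control measures (3'/5' ratios of Actin, GAPDH and ubiquitin in 2 generations of control probe sets, and 2 spike-in signals) were compared by exact permutation tests of the 6 water against the 6 gibberellin arrays. The ratios were also set side by side for the A and B arrays after their values had been seen, without a test.

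The tests, the rule for naming genes and 20 gene lists were fixed before the data were examined. The fixed list of cytosolic ribosomal proteins was set by a name pattern that matched 27 genes. Of these, 0 had a probe set that names them alone, and a ribosomal list by locus was added later. The other fixed lists hold 274 entries. Of the entries, 8 were dropped because the reference table gives the locus another name, and 43 have a probe set that names them alone, so the coverage is under 80% and the lists speak only for the members measured. Among the 43 are 6 of 16 genes of gibberellin perception and signalling, 10 of 20 expansins and 10 of 33 XTH genes. So are 4 of 19 of lipid mobilisation and 3 of 12 of photosynthesis. These 5 lists had at least 3 members after the filter and were tested as groups. The other entries lie in lists of seed storage, DNA replication, ethylene, auxin, heat shock and seed coat flavonoid genes, which were too short for this test. A further 27 tested lists of gene families were added after the annotation had been seen and before any fold change was computed, which makes 32. The group test was camera with its preset correlation of 0.01, adjusted over the 32 lists of a comparison. The same test with an estimated correlation left 0 lists past the threshold in every comparison, and its p is given beside each call.

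For each contrast the rule names the 10 genes with the largest rise and the 10 with the largest fall among probe sets that name exactly 1 gene, pass the test and whose arrays do not overlap between the groups (for the average, whose difference has 1 sign at each time). It also names up to 4 passing members of each list with the largest change, or 2 as values where none passes, and a set of genes of gibberellin synthesis and response. Of that set, GID1A, GID1B and GID1C are given; GA20ox1, GA20ox2, GA20ox3, GA3ox1, GA3ox2, GA2ox1, GA2ox2, RGL2, SCL3 and GA1 were not analysed here.

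The procedure was tested on simulated data with 200 changed probe sets among 15766. At 9 h it recovered 1.5% of changes of 1 on the log2 scale with 0 false calls, and 64% of changes of 2 with 8 false calls. For the average it recovered 57% of changes of 1 with 7 false calls, and 84.5% of changes of 2 with 11 false calls. A gene that did not pass at a single time can therefore have changed by that size.

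Alternatives were quantile normalization, median centring, no filter on low signals, a filter at the 60th percentile, log2(signal + 16), moderation without a trend or with robust variances, fits to the arrays compared only, probe sets that name exactly 1 gene only, the replicate letter as a block, and leaving out each array in turn. The signal ceiling was found in the data, so its use as a block, with arrays whose highest signal is under 4000 against the others, and the fits within each class were added after seeing the data. Within a class the average was fitted with treatment and time but no interaction, so it weights the times by their arrays. For the other contrasts within the 8 arrays with the high ceiling the fit with 6 group means leaves 2 residual degrees of freedom, both from the 9 h groups. Where an array was left out, the remaining array of its group was assumed to vary like the other groups. Summaries and plots were made with the R package data.table in version 1.17.8, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.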

Results

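Transcript levels were measured in seeds of Arabidopsis thaliana in the Ler background after incubation with water or with 5 µM gibberellin, the hormone that promotes germination. Seeds were sampled after 3, 6 and 9 h, with 2 arrays (A and B) for each treatment and time. This makes 6 groups and 12 arrays. Each array gave a signal for 22746 probe sets besides the hybridisation controls. Of these, 15766 (69.3%) were bright enough on at least 2 arrays to be tested. The trimmed mean signal was 100 on every array. The correlation of log2 signals between the 2 arrays of a group lay between 0.913 (gibberellin, 9 h) and 0.935 (gibberellin, 6 h). The number of arrays limits the precision: the median standard error of a log2 change at a single time was 0.317. The labels do not say whether the 2 arrays of a group came from separate batches of seeds, so the p-values measure the spread between these arrays only.

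The arrays differed in a way that the groups do not explain. On 4 arrays (the A arrays of water and gibberellin at 3 h and at 6 h) the highest signal lay between 3308 and 3787, and on the other 8 it lay between 6511 and 9143. Water and gibberellin were represented equally among the 4 arrays with the low ceiling. In a principal component analysis of log2 signals the first component held 26.1% of the variance. The second held 13.9% and separated the A from the B arrays. The ratio of 3' to 5' signal of the Actin control, a measure of RNA integrity, was 1.26 ± 0.158 in water and 1.31 ± 0.0709 in gibberellin (SD, n = 6 each). The two-sided exact permutation p was 0.582, and 0.963 after Benjamini-Hochberg adjustment over 8 control measures. That of GAPDH was 0.903 ± 0.102 and 0.984 ± 0.109 (SD, n = 6 each; two-sided exact permutation p = 0.221, adjusted p = 0.963). An older set of Actin probes gave ratios of 7.4 ± 2.56 in water and 7.35 ± 1.55 in gibberellin (adjusted p = 0.985). In this set the ratio was 5.73 ± 0.835 on the A arrays and 9.01 ± 1.36 on the B arrays (SD, n = 6 each), and that of ubiquitin was 1.48 ± 0.21 and 2.28 ± 0.484. The GAPDH ratio of the older set was 1.19 ± 0.156 and 1.18 ± 0.0993. In the newer set the A and B means were 1.26 and 1.32 for Actin, 0.911 and 0.977 for GAPDH and 1.56 and 2.46 for ubiquitin.

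**Figure D1:**
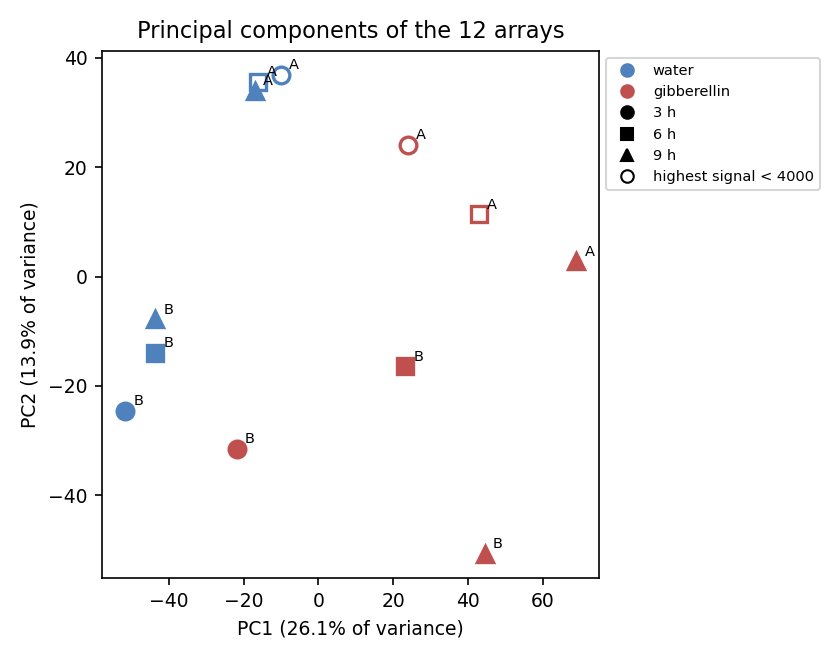
Principal components 1 (horizontal axis, 26.1% of the variance) and 2 (vertical axis, 13.9%) of the log2 signals of the 12 arrays, with treatment by colour, time by symbol, the replicate letter beside each point, and open symbols for the 4 arrays whose highest signal was under 4000. The A arrays lie above 0 on the second component and the B arrays below it.

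The comparison at 3 h asked which transcripts differed early in seeds given gibberellin. EXPA8 (AT2G40610), an alpha-expansin that loosens cell walls, rose from a signal of 75.1 ± 4.16 in water to 801 ± 132 in gibberellin (SD, n = 2), a log2 change of 3.40 ± 0.268 (SE; adjusted p = 0.000306). CP1 (AT4G36880), a cysteine proteinase, rose from 198 ± 34.7 to 1941 ± 695, a log2 change of 3.25 ± 0.274 (adjusted p = 0.000322). ASPGB1 (AT3G16150), an asparaginase, rose by 2.85 ± 0.343 (adjusted p = 0.00494). AT5G55050 rose by 2.71 and SAG29 (AT5G13170), a SWEET sugar transporter, by 2.48 ± 0.351. The named genes that fell were AT3G25260 (-2.05 ± 0.31, adjusted p = 0.0215), AT1G19530 (-1.47) and AT2G28400 (-1.3). AOP3 (AT4G03050), an oxygenase of glucosinolate synthesis, fell as well (-1.35 ± 0.205, adjusted p = 0.0216). AT2G22420, AT3G11600, AT5G11420, AT1G77280 and AT3G03170 rose by between 1.18 and 1.82. Of the 12 fits that leave out 1 array, AT5G11420 and AOP3 passed in 6, AT2G28400 in 2, AT2G22420, AT3G11600 and AT3G03170 in 1 each and AT1G77280 in 0. Without an intensity trend 2 of the 14 named genes, EXPA8 and CP1, kept their calls. With median centring 6 of the 14 lost them: AT1G19530, AT2G28400, AT5G11420, AT3G11600, AT1G77280 and AT3G03170. Of the 14, 1 (EXPA8) passed in all of these fits and in the 11 other settings applied to single genes.

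Among the gene lists at 3 h, 1 of the 6 tested expansins passed the test over all probe sets, and 3 rose when adjusted over the list alone. The median log2 change of the list was 1.14 (camera, adjusted p = 1.59e-05, and adjusted p = 0.482 with an estimated correlation). The wider list of expansins and expansin-like genes adds EXPB2 (-2.64), EXLA1 (-1.17), EXPB5 (-0.64) and EXLB1 (-0.56). With camera it did not pass at 3 h without a block. It passed with the replicate letter (adjusted p = 0.0241) or the signal ceiling (adjusted p = 0.0373) as a block. The list of gibberellin perception and signalling had 6 tested members with a median of -0.27 (adjusted p = 0.0934). Of these, 0 passed over all probe sets with limma and 2 fell when adjusted over the list alone. Its receptor GID1A (AT3G05120) had a log2 change of -0.69 ± 0.214 (adjusted p = 0.587) and the F-box gene SLY1 (AT4G24210) one of -0.71 ± 0.199 (adjusted p = 0.437). For the 6 xyloglucan endotransglucosylase/hydrolases (XTH), which remodel the xyloglucan of the cell wall, the median was 0.46 (adjusted p = 0.316). In all, limma called 36 of 15766 probe sets, 29 higher and 7 lower with gibberellin. Of these, 35 changed at least 2-fold and 15 have 1 gene name. Of all tested probe sets 829 had an unadjusted p under 0.05, where chance would give 788. In water 291 did between 3 h and 6 h, so 788 may be too high a baseline for this model. The count of calls was 66 with the signal ceiling as a block and 110 with the replicate letter as a block. It was 14 among probe sets that name exactly 1 gene and 6 without an intensity trend, and the arrays of the 2 groups alone gave 1, EXPA8. Without the water 3 h B array it was 15, without water 6 h A 22 and without water 6 h B 21. Within the 8 arrays with the high ceiling, where the spread comes from the 9 h groups alone, 6 passed, 5 of them among the 36.

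At 6 h the question was the same with 3 more hours of treatment. ASPGB1 rose by 4.58 ± 0.343 on the log2 scale, and CP1 by 4.26 ± 0.274 (adjusted p = 1.69e-05). EXPA8 rose by 3.98 ± 0.268 (adjusted p = 1.83e-05), from a signal of 74.5 ± 32.9 to 1120 ± 40.9 (SD, n = 2). The serine carboxypeptidase-like genes scpl44 (AT1G43780; 4.55 ± 0.925, adjusted p = 0.0353) and scpl20 (AT4G12910; 3.23 ± 0.586, adjusted p = 0.0194) rose. So did AT3G15720 (4.50), AT5G45670 (3.01), AT5G55050 (2.94) and BPEp (AT1G59640), a basic helix-loop-helix gene (3.3). XERICO (AT2G04240), a RING-H2 gene known to raise abscisic acid levels when overexpressed, fell from 1169 ± 18 to 280 ± 62.6 (SD, n = 2), a log2 change of -2.08 ± 0.211 (adjusted p = 0.000524). AT3G25260 (-2.97), AT1G17830 (-3.02), AT2G28400 (-2.65), AT1G25275 (-2.03), AOP3 (-1.89), AT1G54120 (-1.88) and AT2G38800 (-1.84) also fell, as did HIS1-3 (AT2G18050), a drought-inducible linker histone (-1.88 ± 0.342, adjusted p = 0.0195). UGT72B3 (AT1G01420), a glycosyltransferase, had a change of -4.54. Its signal in gibberellin was 0.983 ± 0.132, far below the brightness filter of 16, and the change was -1.20 on the scale of log2(signal + 16).

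Of the 6 expansins, 3 rose at 6 h, over all probe sets and also adjusted over the list alone. They were EXPA9 (AT5G02260; 4.02 ± 0.871, adjusted p = 0.0458), EXPA8 and EXPA15 (AT2G03090; 1.28 ± 0.22, adjusted p = 0.0156). EXPA9 passed in 4 of the 12 fits that leave out 1 array, and not without an intensity trend, with robust variances or among probe sets that name exactly 1 gene. Of the other genes named at 6 h, AT5G45670 and AT2G38800 passed in 4 of these 12 fits, BPEp in 5 and scpl44 and SLY1 in 6. Without an intensity trend 14 of the 25 genes named at 6 h lost their calls, GID1A, SLY1, EXPA9, EXPA15, XTH19, XTH16, both serine carboxypeptidase-like genes and HIS1-3 among them. The 11 that kept them include ASPGB1, CP1, EXPA8, AT3G15720, XERICO, AT3G25260, AT2G28400 and AOP3. With robust variances scpl44, scpl20 and AT5G45670 did not pass, and with median centring SLY1 and AT2G38800 did not. The median of the list was 1.54 (camera, adjusted p = 1.06e-05; adjusted p = 0.198 with an estimated correlation). Of the 6 XTH genes, 2 rose (2 adjusted over the list alone), XTH19 (AT4G30290) by 1.97 ± 0.329 and XTH16 (AT3G23730) by 1.86 ± 0.371. The median was 1.41 (adjusted p = 0.00524; adjusted p = 0.198 with an estimated correlation). Of the 6 genes of gibberellin perception and signalling, 2 fell (3 adjusted over the list alone). GID1A fell from 370 ± 30.4 to 148 ± 20.4 (SD, n = 2; log2 change -1.33 ± 0.214, adjusted p = 0.0105). SLY1, which targets DELLA repressors for degradation, changed by -0.99 ± 0.199 (adjusted p = 0.033). The median of that list was -0.61 (adjusted p = 0.00242; adjusted p = 0.198 with an estimated correlation). At this time limma called 233 probe sets, 144 higher and 89 lower. Of these, 206 changed at least 2-fold and 104 have 1 gene name. Of all tested probe sets 1816 had an unadjusted p under 0.05. The count was 505 with the signal ceiling as a block, 857 with the replicate letter as a block, 81 without an intensity trend and 90 among probe sets that name exactly 1 gene. Within the 8 arrays with the high ceiling it was 67, of which 52 were among the 233. Leaving out water 6 h A gave 120 calls, water 6 h B 67, gibberellin 6 h A 80 and gibberellin 6 h B 98.

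**Figure D2:**
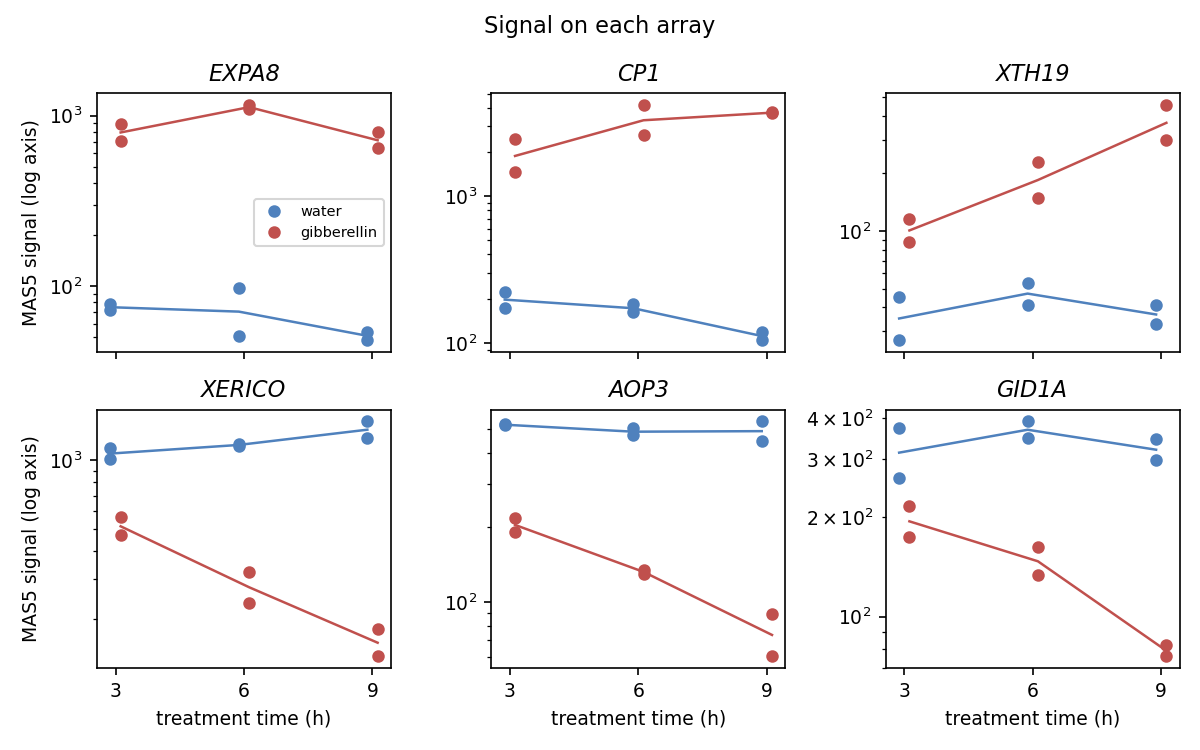
Signals (vertical axis, log scale, deposited MAS5 units) of EXPA8, CP1, XTH19, XERICO, AOP3 and GID1A after 3, 6 and 9 h (horizontal axis) in water and gibberellin; points are single arrays and lines join the geometric means of the 2 arrays. At 9 h CP1 had a mean signal of 3705 with gibberellin and 112 with water, and XERICO one of 159 with gibberellin and 1369 with water.

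After 9 h the largest rises among named genes were those of AT3G15720 (5.91 ± 0.619 on the log2 scale, adjusted p = 0.000347) and scpl44. The latter went from a signal of 27.9 ± 18 in water to 1408 ± 305 in gibberellin (SD, n = 2; log2 change 5.80 ± 0.925, adjusted p = 0.00414). CP1 rose from 112 ± 9.53 to 3705 ± 53.7 (log2 change 5.06 ± 0.274, adjusted p = 3.53e-06), and EXPA9 from 25 ± 16.2 to 481 ± 132 (4.41 ± 0.871, adjusted p = 0.0119). XERICO fell from 1369 ± 162 to 159 ± 30.3, a log2 change of -3.11 ± 0.211 (adjusted p = 1.56e-05). BGLU19 (AT3G21370), a beta-glucosidase, fell from 356 ± 19.5 to 31.2 ± 6.01, a log2 change of -3.52 ± 0.764 (adjusted p = 0.0185). NDB3 (AT4G21490), a mitochondrial NAD(P)H dehydrogenase, rose by 5.20 ± 1.31 (adjusted p = 0.0346), and passed in 6 of the 12 fits that leave out 1 array. Further rises were those of AT3G48460 (5.12), AT4G26790 (4.77), AT1G73050 (4.75), AT5G51440 (4.74) and scpl48 (4.43). Further falls were those of AT5G55750 (-4.33), AT2G24600, AT5G04010, AT2G28400 (-2.98), AT5G59170, AT3G21380, AT5G36160 and AT3G25950 (-2.82). For 7 of the 10 genes with the largest rises, the mean water signal was under 16, so those sizes depend on values near the floor. All 10 passed with log2(signal + 16). Without an intensity trend 7 of the 28 genes named at 9 h lost their calls: NDB3, AT3G48460, AT5G51440, EXPA9, BGLU19, AT3G21380 and SPY. NDB3 and BGLU19 lost them with robust variances too, and AT3G48460, AT1G73050, AT2G24600, AT5G04010 and AT3G25950 in the fit to the arrays of the 2 groups alone. Of the 10 largest falls, 4 had a gibberellin signal under 16, and 8 passed with log2(signal + 16); AT5G04010 and AT3G25950 did not.

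In the list of gibberellin perception and signalling, 4 of 6 tested members fell at 9 h, and the same number when adjusted over the list alone. GID1A fell from 322 ± 33.1 to 78.8 ± 4.18 (SD, n = 2; log2 change -2.03 ± 0.214, adjusted p = 0.000363). GID1C (AT5G27320), another receptor gene, changed by -1.48 ± 0.369 (adjusted p = 0.0328). SLY1 changed by -1.32 ± 0.199 (adjusted p = 0.00295) and SPY (AT3G11540), a repressor of gibberellin responses, by -0.81 ± 0.18 (adjusted p = 0.02). GID1C no longer passed with log2(signal + 16), with no filter on low signals or with the arrays of the 2 groups alone. GID1B (AT3G63010) had a change of -0.88 ± 0.685 (adjusted p = 0.516) and SLY2 (AT5G48170) one of -0.68 ± 0.49 (adjusted p = 0.471). The list median was -1.10 (camera, adjusted p = 8.01e-05; adjusted p = 0.119 with an estimated correlation).

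Of the expansins, 3 of 6 rose at 9 h over all probe sets (EXPA9, EXPA8 by 3.81 ± 0.268 and EXPA15 by 1.62 ± 0.22) and 5 when adjusted over the list alone. Their median was 2.71 (adjusted p = 3.74e-05; adjusted p = 0.186 with an estimated correlation). XTH19 rose from 36.9 ± 6.05 to 375 ± 110 (SD, n = 2; log2 change 3.32 ± 0.329, adjusted p = 0.000241) and XTH16 by 2.29 ± 0.371 (adjusted p = 0.00434). This made 2 of 6 XTH genes over all probe sets and 3 adjusted over the list alone. The median was 2.10 (adjusted p = 0.00397; adjusted p = 0.186 with an estimated correlation). No member of the lists of lipid mobilisation and of photosynthesis passed with limma. In the former, ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, had a change of 0.16 ± 0.821 and SDP1 (AT5G04040), an oil body lipase, one of 0.34 ± 0.2. SDP1-LIKE (AT3G57140) had one of -0.32 and AIM1 (AT4G29010) one of -0.26. The median of 4 members was -0.05 (camera, adjusted p = 0.921). For 3 photosynthesis genes the median was -0.42 (adjusted p = 0.735). The largest change was that of PORB (AT4G27440), which was positive (1.05). RCA (AT2G39730), rubisco activase, had a change of -0.42 ± 0.576 and LHCB4.1 (AT5G01530), a light-harvesting protein, one of -0.76 ± 0.366. Both lists also had 0 members when adjusted over the list alone with limma.

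At 9 h limma called 1178 probe sets, 597 higher and 581 lower. The larger part was the lower one with median centring (427 higher, 570 lower), with the signal ceiling as a block (944 and 1052) and among probe sets that name exactly 1 gene (263 and 300). Of the 1178, 820 changed at least 2-fold and 598 have 1 gene name. Of all tested probe sets 3505 had an unadjusted p under 0.05. The count was 1996 with the signal ceiling as a block and 946 within the 8 arrays with the high ceiling, of which 808 were among the 1178. It was 2691 with the replicate letter as a block, 639 without an intensity trend and 563 among probe sets that name exactly 1 gene. It was 466 without water 9 h A, 256 without water 9 h B, 445 without gibberellin 9 h A and 643 without gibberellin 9 h B.

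**Figure D3:**
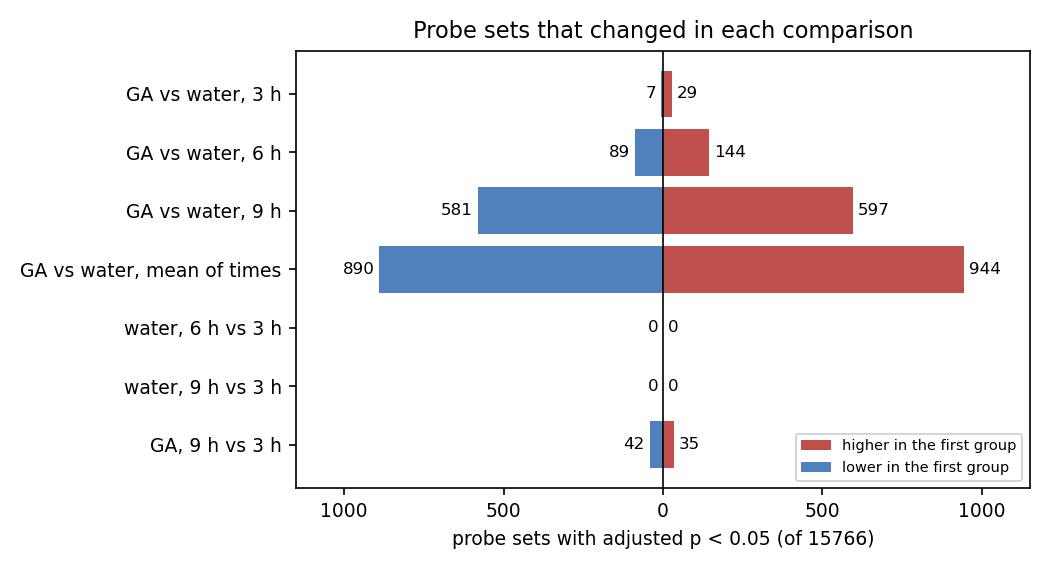
Number of probe sets past an adjusted p of 0.05 (horizontal axis) in each comparison (vertical axis), with bars to the right for those higher and to the left for those lower. With gibberellin, 36 passed at 3 h, 233 at 6 h and 1178 at 9 h, and 0 passed between times in water.

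Averaged over the 3 times, the comparison asked which transcripts gibberellin moved across the whole period. CP1 rose by 4.19 ± 0.158 (SE; adjusted p = 5.68e-08) and EXPA8 by 3.73 ± 0.155 (adjusted p = 8.13e-08), each with 6 arrays per treatment. AT3G15720 (4.49), scpl44 (4.33), ASPGB1 (3.82 ± 0.198, adjusted p = 5.16e-07), NDB3 (3.81), AT4G26790 (3.62), EXPA9 (3.58), AT5G02550 (3.47) and AT1G33750 (3.31) also rose. XERICO fell by 2.08 on the log2 scale (SE 0.122, adjusted p = 1.6e-06). Falls were also seen for AT5G55750 (-2.52), AT3G25260 (-2.49), AT3G49480 (-2.35), AT2G28400 (-2.31), BGLU19 (-2.29), UGT84A4 (-2.18), UGT72B3 (-2.13), AT3G20530 (-2.09) and AOP3 (-1.99). AT5G02550 lost its call with quantile normalization, with median centring and with either block, and AT3G20530 with no filter on low signals and without an intensity trend. Of the 12 fits that leave out 1 array, each of these 2 passed in 1 and UGT84A4 in 5. For 6 of the 10 largest rises and 5 of the 10 largest falls the lower signal was under 16, so those sizes are uncertain, and all 20 passed with log2(signal + 16).

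Of the 6 genes of gibberellin perception and signalling, 4 fell in the average, the same number as when adjusted over the list alone. They were GID1A (-1.35 ± 0.124, adjusted p = 5.9e-05), SLY1 (-1.01 ± 0.115, adjusted p = 0.000245), GID1C (-0.85 ± 0.213, adjusted p = 0.0244) and SPY (-0.49 ± 0.104, adjusted p = 0.0103). GID1B had a change of -0.49 ± 0.396 (adjusted p = 0.502). The median was -0.67 (camera, adjusted p = 0.000447; adjusted p = 0.182 with an estimated correlation). Of the expansins 4 of 6 rose (4 adjusted over the list alone). Besides EXPA8, EXPA9 and EXPA15 these include EXPA4 (AT2G39700; 2.37 ± 0.678, adjusted p = 0.0429), whose call was lost without an intensity trend or with robust variances and held in 3 of the 12 fits that leave out 1 array. The median was 1.82 (adjusted p = 2.07e-05; adjusted p = 0.227 with an estimated correlation). The XTH genes gave 2 of 6 (3 adjusted over the list alone) with a median of 1.01 (adjusted p = 0.00883; adjusted p = 0.239 with an estimated correlation). From the shorter lists, EIN3 (AT3G20770), the transcription factor of ethylene signalling, fell (-0.47 ± 0.112, adjusted p = 0.0185). PRL (AT4G02060), a subunit of the MCM helicase of DNA replication, rose (0.91 ± 0.254, adjusted p = 0.0387). The call of PRL was lost with median centring and with no filter on low signals, and held in 3 of the 12 fits that leave out 1 array. That of EIN3 was lost without an intensity trend and held in 9 of them, and that of GID1C held in 5. OLEO3 (AT5G51210), an oleosin, had an average change of -0.20 ± 0.234 and LEA4-5 (AT5G06760), a late embryogenesis abundant protein, one of -0.31 ± 0.17. IAA18 (AT1G51950), an auxin-response repressor, had one of 0.27 ± 0.239 and DFR (AT5G42800), an enzyme of seed coat flavonoids, one of -0.03 ± 0.436. None of these 4 passed with limma.

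In the average limma called 1834 probe sets, 944 higher and 890 lower (780 and 807 with median centring). Of these, 508 changed at least 2-fold and 941 have 1 gene name. Within the 8 arrays with the high ceiling, in a fit of treatment and time without interaction that leaves 4 residual degrees of freedom, 1163 passed, 1062 of them among the 1834. The 4 arrays with the low ceiling are from 3 h and 6 h only, 1 per group, so the same kind of fit averages 2 times there and leaves 1 residual degree of freedom; 844 passed there, 671 of them among the 1834. The fit with the ceiling as a block called 2689, and that with the replicate letter as a block 3446. Over all 15766 probe sets the effects in the 2 classes of arrays, over 2 and over 3 times, had a Pearson correlation of 0.537. Without water 9 h B the count was 1125, without gibberellin 6 h A 1178, and among probe sets that name exactly 1 gene 922.

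The gibberellin effects at 3, 6 and 9 h were then compared with each other; these comparisons share no arrays. All 36 probe sets called at 3 h kept their direction at 6 h and at 9 h. Of the 29 higher at 3 h, 27 were called higher at 6 h and 28 at 9 h, with median log2 changes of 2.45, 2.65 and 2.40 at the 3 times. The 7 that were lower at 3 h were called lower at both later times, with medians of -1.35, -2.23 and -2.74. Of the 144 called higher at 6 h, 135 were called higher at 9 h, where independent lists would share 5.45. Of the 89 called lower, 77 were called lower at 9 h, where 3.28 would be shared. No probe set was called in opposite directions at any pair of times.

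Across probe sets, which are not independent replicates, the log2 changes at 6 h and 9 h had a Pearson correlation of 0.504 (Spearman 0.507). The values were 0.320 (0.360) for 3 h and 6 h and 0.312 (0.367) for 3 h and 9 h. With no filter on low signals the Pearson values were 0.205, 0.123 and 0.110 in the same order. With log2(signal + 16) they were 0.732, 0.562 and 0.549. Leaving out gibberellin 3 h A gave 0.142 for 3 h and 6 h and 0.133 for 3 h and 9 h.

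A test of the difference between the gibberellin effects at 9 h and at 3 h asked which effects grew with time. It called 2 probe sets, both more strongly lower at 9 h and neither with a gene name in the annotation used. They are given because they are the only 2 calls of the main model, which has no block, and were chosen after their values were seen. One fell with gibberellin from 528 ± 11.3 to 269 ± 16.5 at 3 h and from 525 ± 41.4 to 39.0 ± 2.6 at 9 h (SD, n = 2). The log2 change went from -0.97 to -3.75, a difference of -2.78 ± 0.229 (adjusted p = 0.00102). The other fell from 1366 ± 30.3 to 659 ± 68.9 at 3 h and from 1574 ± 69.8 to 189 ± 27.6 at 9 h, a difference of -2.01 ± 0.243 (adjusted p = 0.0275). For named genes the differences did not pass in this model, which has no block: that of XERICO was -2.05 ± 0.299 (adjusted p = 0.104), that of GID1A -1.33 ± 0.303 (adjusted p = 0.298) and that of CP1 1.80 ± 0.388 (adjusted p = 0.265).

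As a group, the genes of gibberellin perception and signalling were lower at 9 h relative to 3 h, with a median difference of -0.83 (camera, adjusted p = 0.000207; adjusted p = 0.161 with an estimated correlation). Singly, 0 passed with limma and 1 was lower when adjusted over the list alone. The XTH genes had a median difference of 1.66 (adjusted p = 0.00474; adjusted p = 0.264 with an estimated correlation), with 3 higher when adjusted over the list alone. The expansins had one of 0.88 (adjusted p = 0.0183; adjusted p = 0.486 with an estimated correlation), with 0 by limma when adjusted over the list alone. In this comparison 1074 probe sets had an unadjusted p under 0.05. With the replicate letter as a block 163 probe sets passed, 61 higher and 102 lower. The 8 arrays with the high ceiling hold 1 array per group at 3 h, the B array, so a fit to them cannot decide about the 2 probe sets called. On those arrays the one with the difference of -2.78 had 520 in water and 281 in gibberellin at 3 h. The one with -2.01 had 1344 and 610. The count of calls was 40 with the signal ceiling as a block and 46 without gibberellin 3 h A. Leaving out any other single array except water 9 h A gave 1, as did quantile normalization, the fit without an intensity trend and the fit to the arrays of the 4 groups alone. With log2(signal + 16) it was 4.

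**Figure D4:**
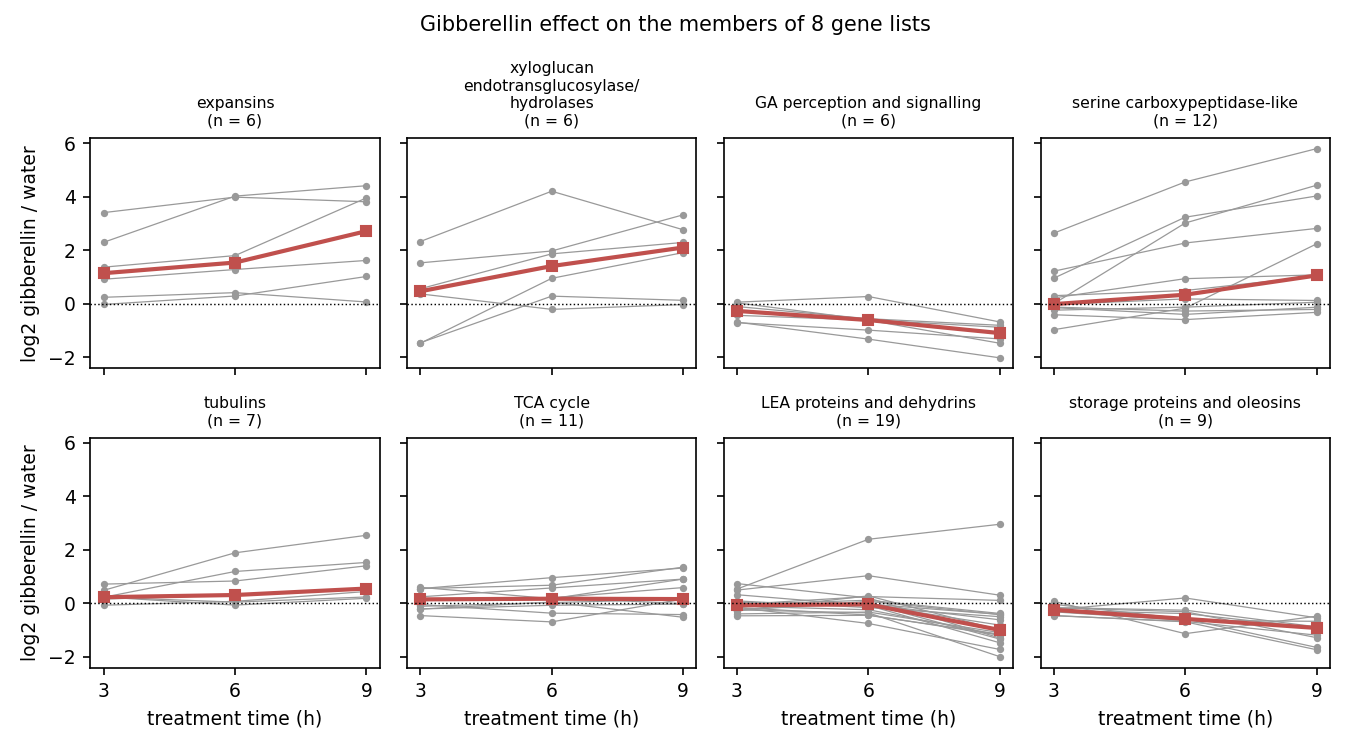
Log2 change with gibberellin against water (vertical axis) at 3, 6 and 9 h (horizontal axis) for the members of 8 gene lists; grey lines are single genes and red lines the list medians. The median of the expansins was 1.14, 1.54 and 2.71 at the 3 times and that of the genes of gibberellin perception and signalling -0.27, -0.61 and -1.10.

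Between 3 h and 9 h of gibberellin treatment, XTH19 rose by 1.87 ± 0.329 (SE; adjusted p = 0.0352) from a signal of 102 ± 20 to 375 ± 110 (SD, n = 2). YLS5 (AT2G38860) rose by 2.29 ± 0.344 (adjusted p = 0.0185), SBT1.3 (AT5G51750), a subtilisin-like protease, by 1.83 ± 0.349 and Fes1B (AT3G53800), a co-chaperone of HSP70, by 1.47 ± 0.275. AT5G59130 (3.02), AT4G32460 (2.2), AT2G22420 (1.58), AT3G15680 (1.44), AT2G17240 (1.32) and AT4G36180 (1.27) rose too. XERICO fell by 1.70 on the log2 scale (SE 0.211, adjusted p = 0.0104) and GID1A fell by 1.3 (SE 0.214, adjusted p = 0.0274). LTI30 (AT3G50970), a dehydrin, fell by 1.85 (SE 0.334, adjusted p = 0.0376). The other large falls were those of AT5G59170 (-2.83), AT5G36160 (-2.26, adjusted p = 0.00527), AT1G14940, AT5G44380, AT2G29340, AT4G33980, AT2G44800 and AT1G25275 (-1.72).

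Between these times the genes of gibberellin perception and signalling had a median of -0.69. There were 1 of 6 past the test over all probe sets and 4 adjusted over the list alone (camera, adjusted p = 0.000138; adjusted p = 0.145 with an estimated correlation). The XTH genes had a median of 1.3, with 1 past the test and 3 adjusted over the list alone (adjusted p = 0.00508; adjusted p = 0.317 with an estimated correlation). The expansins had one of 0.85, with 0 past limma's test and 2 adjusted over the list alone (adjusted p = 0.0159; adjusted p = 0.451 with an estimated correlation). In all, 77 probe sets passed, 35 higher and 42 lower at 9 h, 75 of them at least 2-fold. The larger part was the higher one with log2(signal + 16) (89 and 57), within the arrays with the high ceiling (181 and 100) and without gibberellin 3 h A (200 and 111). Of the 12 fits that leave out 1 array, GID1A passed in 4, XTH19, SBT1.3, Fes1B, AT2G22420, AT5G59130 and AT1G14940 in 3 each, AT4G32460 in 1, AT2G44800 in 4 and LTI30 in 5. The count was 850 with the signal ceiling as a block, 281 within the 8 arrays with the high ceiling (56 of the 77 among them), 146 with log2(signal + 16), and 37 among probe sets that name exactly 1 gene. It was 1024 with the replicate letter as a block. It was 5 without an intensity trend and 2 from the arrays of the 2 groups alone, and in these 2 fits every gene named here for this comparison lost its call. It was 311 without gibberellin 3 h A and 9 without gibberellin 3 h B, and 24 without gibberellin 9 h A or B. It was 36 without water 9 h A, 32 without water 9 h B, 43 without water 6 h A or gibberellin 6 h B, and 42 without water 6 h B or gibberellin 6 h A.

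In water alone, the comparisons asked what changed with time and no hormone. GID1A had signals of 319 ± 78.1, 370 ± 30.4 and 322 ± 33.1 at 3, 6 and 9 h (SD, n = 2), and XERICO signals of 1073 ± 82.8, 1169 ± 18 and 1369 ± 162. With limma 0 probe sets passed between 3 h and 6 h (291 with an unadjusted p under 0.05) and 0 between 3 h and 9 h (326), where chance would give 788 each. Both numbers lie under chance, as when p-values run too high, so 0 calls do not show that nothing changed. Every other setting also gave 0 for 6 h. For 9 h all gave 0 except the replicate block, with 2. No gene list passed between 3 h and 6 h with camera. Between 3 h and 9 h, the 68 plastid-encoded genes had a median of 0.31 (adjusted p = 7.07e-06; adjusted p = 0.95 with an estimated correlation). For 23 nuclear genes of photosynthesis and chlorophyll it was 0.13 (adjusted p = 0.0242; adjusted p = 0.95 with an estimated correlation). LEA proteins (0.19, adjusted p = 0.0084) and cytosolic ribosomal proteins (0.11, adjusted p = 0.0242) also passed (adjusted p = 0.95 with an estimated correlation for both). Both medians changed sign with the signal ceiling as a block, and the ribosomal list did not pass with quantile normalization (adjusted p = 0.957). The fixed lists did not pass between 3 h and 9 h, with adjusted p of 0.912 for gibberellin perception and signalling, 0.9 for the XTH genes and 0.686 for photosynthesis. With the signal ceiling as a block the photosynthesis list passed (adjusted p = 0.0326).

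The last comparison asked whether transcripts that moved with gibberellin moved alike with time in water, on arrays not shared between the effects. Across probe sets, the gibberellin effect at 9 h had a Pearson correlation of -0.00914 (Spearman 0.00952) with the change from 3 h to 6 h in water. The effect at 3 h had one of -0.0188 (Spearman -0.0553) with the change from 6 h to 9 h. XERICO, which fell with gibberellin at 9 h, had a change of 0.35 ± 0.211 from 3 h to 9 h in water (adjusted p = 1), and CP1 one of -0.82 ± 0.274 (adjusted p = 1). Both correlations changed sign when single arrays were left out. The first was 0.043 without water 3 h A and -0.0738 without water 3 h B. The second was 0.00774 without water 3 h B and 0.0115 without water 6 h A. In the main model no probe set passed in water between 3 h and 6 h or between 3 h and 9 h. The changes in water may therefore be mostly spread between arrays. A weak correlation with them does not show that the gibberellin effect is unrelated to time in water.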

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

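The fits and the test that use the signal ceiling, the test of RNA quality and the test on probe sets called at 6 h were chosen only after the data were seen. Every other test given here was set before the result it measures. The counts and the changes of the strongest named genes at each time had been seen by then.

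The test of the gibberellin effect at 9 h against that at 3 h picked out 2 single probe sets that have no gene name in the annotation used. The 8 arrays with the high ceiling hold 1 array per group at 3 h, so a fit to them cannot decide about these 2. On those arrays at 3 h the former had a signal of 610 with gibberellin and 1344 in water, and the latter 281 and 520. In the fit to all arrays the former had a difference of -2.01 (adjusted p = 0.0275) and the latter one of -2.78 (adjusted p = 0.00102), on the log2 scale with limma. The same test picked out groups of genes by camera with the preset correlation. With an estimated correlation none of them passed. Groups with a lower median at 9 h than at 3 h were gibberellin perception and signalling (-0.83; adjusted p = 0.000207, or adjusted p = 0.161 with an estimated correlation) and, with the p-values in the same order, LEA proteins and dehydrins, which protect dry seeds (-0.70; 6.9e-05, or 0.596). Others were storage proteins and oleosins (-0.72; 0.0091, or 0.62) and bZIP transcription factors (-0.37; 0.0355, or 0.264). The call of the bZIP group was lost with quantile normalization, at an adjusted p of 0.0951. Groups with a higher median were the fixed list of expansins (0.88; 0.0183, or 0.486) and the wider family of expansins and expansin-like genes (1.08; 0.0101, or 0.276). The XTH genes, the same 6 members in the fixed and in the family list, were also higher (1.66 in both; 0.00474, or 0.264). Further ones were cytosolic ribosomal proteins (0.21; 6.9e-05, or 0.698), serine carboxypeptidase-like genes (0.80; 0.000103, or 0.264) and tubulins (0.51; 0.0107, or 0.264). Median centring shifted the median of all probe sets in this comparison to -0.12, and that for gibberellin at 9 h against 3 h to -0.10. That shift is the same for every probe set and smaller than each group median above, so the signs of those medians were fixed in advance. The group test was not run with median centring.

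The pattern weighed is the rise in called probe sets from 36 at 3 h to 233 at 6 h and 1178 at 9 h. The low signal ceiling of 1 array per group at 3 h and 6 h could have hidden early effects, and this stays open. None of the B arrays has it. There the effect at 9 h had 2.18 times the covariance with the effect at 6 h that the effect at 3 h had (bound 1.5). The covariances with the B effect at 6 h were 0.112 at 3 h and 0.244 at 9 h in the B arrays. In the A arrays, which have the low ceiling at 3 h, they were 0.13 at 3 h and 0.254 at 9 h. These are single arrays without a spread, so the values cannot decide. RNA quality at 9 h stays open: the mean 3'/5' ratios of Actin and GAPDH differed by at most 1.3-fold between treatments, under a bound of 1.5, but the largest fold within a letter was 1.41, and with 2 letters the t intervals of 2 of the 4 ratios pass the bound. Of the 233 probe sets called at 6 h, 231 had the same sign at 3 h and 209 lay further from water at 9 h than at 3 h (205 in the A and 210 in the B arrays). A response that grows with time needs this, but the share among all probe sets was not measured. More of them moved at 9 h than at 3 h anyway (3505 against 829 with an unadjusted limma p under 0.05). Of the 36 called at 3 h, 18 lay further at 9 h than at 6 h (exact binomial p = 1). The explanation that early genes respond further at 9 h asked for more than this, so its prediction was not met. The probe sets share arrays and are not independent replicates, so the binomial test is a rough guide and does not decide.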

How the results depend on the processing

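The fits with the signal ceiling were chosen only after the data were seen. No count of calls was changed by more than 1.5 times by robust variances, median centring, the 60th-percentile filter or no filter. No named gene reversed in the settings run for single genes, which leave out the fits within 1 ceiling class. Without an intensity trend 57 calls of named genes were lost, and 43 in fits to the arrays compared only. The former were 12 of 14 at 3 h, 14 of 25 at 6 h, 7 of 28 at 9 h and 3 of 30 in the average. For gibberellin at 9 h against 3 h they were 21 of 21. The latter were 13 of 14, 3 of 25 and 6 of 28 at the 3 times, and again 21 of 21 for gibberellin at 9 h against 3 h. Further calls were lost with 1 array left out. The causes were not tested, except that fewer arrays or fewer probe sets enter some fits. Signal over background was not measured; large changes that involve signals under 16, the filter, are the least certain in size.

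In the order 3 h, 6 h, 9 h, the gibberellin counts of 36, 233 and 1178 became 6, 81 and 639 without an intensity trend. They were 14, 90 and 563 among probe sets that name exactly 1 gene (fewer are tested), 66, 505 and 1996 with the ceiling block, and 6, 67 and 946 within the high-ceiling arrays. At 3 h the arrays compared alone gave 1. The average of 1834 became 922 with 1 gene per probe set and 1163 within the high-ceiling arrays; the low-ceiling arrays, of 3 h and 6 h only, gave 844 for 2 times. The difference between 9 h and 3 h, 2 calls, became 1 with quantile normalization, 4 with log2(signal + 16), and 1 without a trend. It was 1 with the arrays compared only, 0 with 1 gene per probe set and 40 with the ceiling block. Within the high-ceiling arrays, with 1 array per group at 3 h, a fit cannot decide about these calls. Gibberellin at 9 h against 3 h, 77 calls, became 146 with log2(signal + 16), 5 without a trend, 2 with the arrays compared only, 37 with 1 gene per probe set, 850 with the ceiling block and 281 within the high-ceiling arrays. The fixed lists passing fell to 0 with an estimated correlation.

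The letters A and B share structure: of 15 pairs of groups, 14 correlated over 0.1 in their deviations, the lowest at 0.077 and the highest at 0.275. Water and gibberellin of the same time correlated at 0.275, 0.169 and 0.103 at 3, 6 and 9 h. The rule used asks for over 0.1 in all 15 pairs, so the main model has no letter. A difference shared by the letters therefore stays in the spread of the main model. A probe set that did not pass there may pass with the letter as a block. With the letter as a replicate block the counts were 110, 857 and 2691 at 3, 6 and 9 h, 3446 for the average, 163 for the difference, 1024 for gibberellin at 9 h against 3 h, 0 for water at 6 h and 2 for water at 9 h. The heat shock list at 9 h passed with it (adjusted p = 0.0471).

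The correlations between times (3 h and 6 h, 3 h and 9 h, 6 h and 9 h) were 0.123, 0.110 and 0.205 with no filter and 0.562, 0.549 and 0.732 with log2(signal + 16). That of the 3 h effect with water was 0.00334 and -0.0634. Between 3 h and 9 h in water, 3 lists reversed with the ceiling block, at adjusted p of 0.343 for ribosomal proteins, 0.81 for LEA proteins and dehydrins, and 0.0257 for storage proteins and oleosins. Ranges with 1 array left out were 15 to 31, 67 to 300 and 256 to 1268 calls at 3, 6 and 9 h, and 1125 to 1905 for the average. They were 1 to 46 for the difference, 0 to 0 in water at both times and 9 to 311 for gibberellin at 9 h against 3 h. For the correlations they were 0.142 to 0.388, 0.133 to 0.384 and 0.363 to 0.526, and with water -0.0738 to 0.043 and -0.047 to 0.0115.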

Other observations

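The fits that use the signal ceiling, where given here, were chosen only after the data were seen; the test of other splits was set before its result.

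At 9 h the gene families added to the fixed lists moved with gibberellin as follows. Of 19 LEA proteins and dehydrins, 5 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone. The median was -1.0 (camera, adjusted p = 0.000158; adjusted p = 0.537 with an estimated correlation). AT3G53040 (-2.00 ± 0.279, adjusted p = 0.00192), AT3G17520 (-1.73 ± 0.362) and LTI30 (-1.3 ± 0.334) fell. The dehydrin COR47 (AT1G20440) rose from a signal of 39.6 ± 5.14 to 314 ± 102 (SD, n = 2; log2 change 2.95 ± 0.468, adjusted p = 0.00402). Among 9 storage proteins and oleosins the median was -0.93 (adjusted p = 0.00265; adjusted p = 0.522 with an estimated correlation) and 1 fell, AT4G36700 by -1.74 ± 0.246. Of 12 serine carboxypeptidase-like genes, 5 rose, with a median of 1.05 (adjusted p = 0.000896; adjusted p = 0.263 with an estimated correlation), scpl20 among them from 141 ± 47.7 to 2244 ± 234. Of 7 tubulins, 2 rose, TUB5 (AT1G20010; 2.54 ± 0.527) and TUB7 (AT2G29550; 1.40), with a median of 0.55 (adjusted p = 0.00197; adjusted p = 0.186 with an estimated correlation). Of 119 cytosolic ribosomal proteins, 8 rose and 0 fell with limma, and the median was 0.24 (adjusted p = 2.34e-05; adjusted p = 0.638 with an estimated correlation).

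Of 11 genes of the TCA cycle, 4 rose at 9 h, SDH2-1 (AT3G27380) by 1.35 ± 0.187, IDH-VI (AT3G09810) by 1.31 ± 0.246, and IDH-V and SDH2-2 by 0.90 each. The median was 0.15 (adjusted p = 0.0339; adjusted p = 0.186 with an estimated correlation). The median of 6 bZIP factors was -0.53 (adjusted p = 0.0104; adjusted p = 0.186 with an estimated correlation), with 0 past limma's test singly and 2 lower when adjusted over the list alone. Of 13 heat shock proteins and co-chaperones, 4 rose, AT5G51440 by 4.74, Fes1B by 1.70, Hop1 by 1.68 and Hop2 by 0.81. The group test did not pass at 9 h (adjusted p = 0.0745). It passed at 6 h (adjusted p = 0.00349; adjusted p = 0.198 with an estimated correlation) and in the average (adjusted p = 0.0125; adjusted p = 0.227 with an estimated correlation). PYK10 (AT3G09260), a beta-glucosidase of ER bodies, rose from 109 ± 22 to 1171 ± 239 (SD, n = 2; log2 change 3.42 ± 0.672, adjusted p = 0.0115), while its relative BGLU19 fell.

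The 1834 probe sets called in the average over the times were set against other splits of the 12 arrays that keep 2 arrays per side at each time, 100 of 108 drawn. As many probe sets were called in 2 of the 100 splits, the real one included, which is under the bound set before the result. The other split called 2263: it keeps the real groups at 6 h and 9 h and, at 3 h, sets the 2 A arrays, which have the low ceiling, against the 2 B arrays. The highest number among the rest was 759, and the split by letter at all times called 704, which points to a structure of the arrays along the letters. The arrays of a time are thus not interchangeable, and the labels do not say whether the 2 of a group are separate batches. The test therefore does not exclude chance differences between batches. With the ceiling as a block the real comparison called 2689 probe sets, and within the high-ceiling arrays 1163. The low-ceiling arrays, which are from 3 h and 6 h only, gave 844 for those 2 times with 1 residual degree of freedom.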
